A study of Homo sapiens with 5 samples.

How the data were processed

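RNA was extracted with Trizol from snap-frozen subcutaneous xenograft tumors, per the labels' protocols. Stranded mRNA libraries were made from 1000 ng of total RNA with a poly-A selection and read as single-end 50 bp reads on a HiSeq2500, per the labels' protocols. Reads were aligned with STAR 2.5.2 and counted per gene with HTSeq 0.10.0 on GRCh38, per the submitters' processing notes. The HTSeq strand setting, the annotation release and the treatment of reads from the mouse host are not given in the sources used here.

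The values deposited are raw counts per gene, with 4 count columns for each library that the file headers name by sequencing lane and read-file part. The columns were summed to 1 count per gene and library. The table held 58051 gene identifiers and 0 rows without a gene. Symbols came from a gene name table that held 56948 of these identifiers, and gene types and positions came from GENCODE 29 on GRCh38, which held 57447 of them (matched without the version suffix).

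The 5 libraries were grouped by their labels as control vector (A, B and C, n = 3) and STAT2 shRNA (B and C, n = 2). The titles call the control an empty vector and the design text describes a scrambled shRNA, so it is called the control vector here. The design text gives 3 tumors per line, and a further STAT2 shRNA tumor was not analysed here. Total counts were 12988103, 12668800 and 50213844 in controls A, B and C and 17008794 and 16045311 in shRNA B and C. A level of 1 CPM, the count scaled to a library total of 1000000, therefore rests on about 13.0 counts in control A and 50.2 in control C, and low levels are less precise in the shallower libraries. Intervals and floors cover counting error only. Within a group, every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom 13.9 to 67.0), whereas the largest pair of columns within a library gave 1.09 to 1.16. No library was a copy of another.

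Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors (0.984 to 1.03), its default filter on low counts with the group, and the quasi-likelihood test without robust dispersion on the group alone. P-values were adjusted with Benjamini-Hochberg over the 16697 genes tested, at 0.05. Fold changes are STAT2 shRNA over control vector, as fitted, and levels are CPM scaled with the TMM factors, as mean ± SD. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 27 lists. The lists, the tests and the rule for named genes were set before the data were examined, as were all alternatives except the thinning of control C. For each list, calls were also counted with p-values adjusted over the list alone.

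The lists were interferon-stimulated genes, interferon receptor and JAK-STAT components, interferon-gamma and IRF1 targets, MHC class I antigen presentation, nucleic acid sensing, NF-kB targets, S-phase and E2F targets, G2/M genes, p53 targets, hypoxia response, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded genes, epithelial identity, mesenchymal transition genes, Wnt targets, MAPK output, immediate-early genes, apoptosis regulators, cholesterol synthesis, unfolded protein response and ATF4 targets, cytosolic ribosomal proteins, 4 sets of host cell markers, and neutral housekeeping genes. Host markers carry human symbols, so reads of the mouse host enter them only where they mapped to the human genome. Named genes were STAT2, and, among called genes with a symbol, a mean of at least 1 CPM and no overlap between the groups, the 10 largest rises, the 10 largest falls and the 5 smallest p-values each way. Up to 4 members of each list with the smallest unadjusted p were named as well. Results for some of these genes are not reported here. Any other gene named was chosen after its values were seen.

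The steps were tested on simulated counts with the real means and library sizes, in 5 rounds with 200 changed genes over a mean of 16279 genes. At this design, 26.1% of the 2-fold and 78% of the 4-fold changes were called and 9.3% of calls were false. All 5 planted lists of 40 genes at 1.5-fold were called, against 0 of 5 random lists. The simulated genes varied independently, so this says nothing about lists whose members vary together.

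Alternatives were RLE, upper-quartile and library-size scaling, other filters on low counts, DESeq2 1.42.0, limma voom, robust dispersion, protein-coding genes alone, removal of mitochondrially encoded genes, the replicate letter as a block, each library left out in turn, and, for lists, an estimated correlation, ranks and fry. Control C thinned to the total of control B was added after seeing the data. Tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.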

Results

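RNA was sequenced from subcutaneous tumors grown from HCT116 cells lacking p53, a human colorectal cancer line, in Rag1-knockout mice, which have no mature B and T cells. The cells carried either a pLKO.1 control vector or a pLKO.1 vector with an shRNA against STAT2. STAT2 is a subunit of ISGF3, the transcription factor complex that type I interferon activates. Tumors were collected on day 21, each from its own mouse, and each group came from a single cell line. Here 3 control tumors (A, B and C) were compared with 2 STAT2 shRNA tumors (B and C). Total counts were 12988103, 12668800 and 50213844 in controls A, B and C, and 17008794 and 16045311 in shRNA B and C. Between 23275 and 27466 genes had at least 1 count per library. The comparison asked which transcripts of the tumors differ when STAT2 is silenced, and its p-values measure the spread between these tumors, not between cell lines made separately.

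The transcript targeted by the shRNA was measured first. STAT2 (ENSG00000170581, a protein-coding gene on GRCh38 chromosome 12, 56341597 to 56360155) stood at 163 ± 39.7 CPM (counts scaled to a library total of 1000000; SD, n = 3) in the control tumors and 105 ± 39.3 CPM (SD, n = 2) in the STAT2 shRNA tumors. The log2 fold change was -0.63 (SE 0.28), with an unadjusted p of 0.0493 and an adjusted p of 0.534 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so the difference was not called. Control A had 170 CPM, control B 120 CPM and control C 199 CPM, against 77.7 CPM in shRNA B and 133 CPM in shRNA C, so shRNA C lay above control B. The STAT2 log2 fold change was -0.29 without shRNA B and -1.08 without shRNA C, and it was called in neither. Because the groups overlapped in STAT2 itself, the libraries are named by their labels, and every direction given here is that of the libraries labelled STAT2 shRNA.

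Interferon-stimulated genes stood lower in the tumors labelled STAT2 shRNA. Of 58 tested members of that list, 52 had a negative log2 fold change, with a median of -0.37, and 33 had both shRNA tumors below all 3 controls and 1 had both above, where chance sets 20% of genes apart in either direction. IFI44L (ENSG00000137959) had the largest fall among the list's named members, from 85.5 ± 22.9 CPM (SD, n = 3) to 6.56 ± 3.11 CPM (SD, n = 2), a log2 fold change of -3.70. RSAD2, which encodes the antiviral protein viperin, fell from 42.5 ± 9.93 CPM to 13.8 ± 4.64 CPM, and IFI44 fell from 183 ± 25.1 CPM to 78.5 ± 15 CPM. The abundant transcript IFI6 stood at 3400 ± 322 CPM and 2010 ± 146 CPM and was not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p 0.183), but was called by DESeq2 (0.0172).

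By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.000741 for IFI44L, 0.0227 for RSAD2 and 0.0255 for IFI44. No other member was called by edgeR, DESeq2 called 4 members and voom 3, and the same number as in edgeR, 3 lower and 0 higher, was called there when adjusted over the list alone. As a list, the interferon-stimulated genes were called lower by camera with the preset correlation, with an adjusted p of 4.34e-10, and were not called with an estimated correlation, with an adjusted p of 0.409. The fry test, which asks only whether the members move on balance in a single direction, gave an adjusted p of 0.135. The mixed form of fry, which counts changes in either direction, gave an adjusted p of 0.0175. That form says nothing about direction, and it also passed 0.05 for the interferon-gamma and IRF1 targets (0.00643), which camera did not call. The list's mean log2 level, relative to its average over the 5 tumors, was 0.15, 0.13 and 0.25 in controls A, B and C and -0.35 and -0.18 in shRNA B and C. With each of the 5 tumors left out in turn, IFI44L remained called in all 5 fits (adjusted p 0.00112 to 0.0127), RSAD2 in 1 (0.0284 to 0.358) and IFI44 in 0 (0.0556 to 0.381).

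Interferon receptor and JAK-STAT components, and interferon-gamma and IRF1 targets, were not called as lists. Among 22 tested members of the former, 11 had positive and 11 negative log2 fold changes, and 0 were called by edgeR, over all genes or adjusted over the list alone (camera adjusted p 0.79). DESeq2 and limma voom also called 0, and 2 had an unadjusted p under 0.05 in edgeR. IRF9, the DNA-binding partner of STAT2 in ISGF3, stood at 11.6 ± 3.03 CPM in controls and 7.54 ± 0.254 CPM in shRNA tumors, while SOCS1, a feedback inhibitor of cytokine signaling, stood at 6.58 ± 1.06 CPM and 10.5 ± 0.00683 CPM; neither was called. The interferon-gamma and IRF1 targets had 17 tested members with a median log2 fold change of 0.07 and 0 calls over all genes, and 2 higher when adjusted over the list alone (camera adjusted p 0.78; 5 at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom). In that list, the log2 fold changes of CASP4, APOL6 and GBP3 were 1.58, 1.04 and -1.01, none of them called by edgeR; DESeq2 called CASP4 (adjusted p 0.0171), as did edgeR over protein-coding genes alone (0.041).

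The sensors of foreign nucleic acid had 16 tested members, 12 of them with a negative log2 fold change, a median log2 fold change of -0.26 and 1 called gene, IFI16. This DNA-binding interferon-inducible gene fell from 8.23 ± 2.64 CPM (SD, n = 3) to 1.66 ± 0.233 CPM (SD, n = 2), a log2 fold change of -2.30 with an adjusted p of 0.0197 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. STING1, the adaptor downstream of cytosolic DNA sensing, stood at 35.4 ± 1.57 CPM and 60.5 ± 0.317 CPM and passed in edgeR only when adjusted over the list alone, where 1 gene was higher and 1 lower, but was called over all genes by DESeq2 (adjusted p 0.0297). IRF7 and IFIH1 had log2 fold changes of -1.21 and -0.45 and were not called; they, RIGI, DHX58, ADAR and EIF2AK2 are also members of the interferon-stimulated list. Camera called the list lower with an adjusted p of 0.02, but not with an estimated correlation, which gave an adjusted p of 0.782. That call ended without control C (adjusted p 0.0696) and without shRNA B (0.153), and IFI16 remained called in 1 of the 5 fits that left out a tumor.

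**Figure D1:**
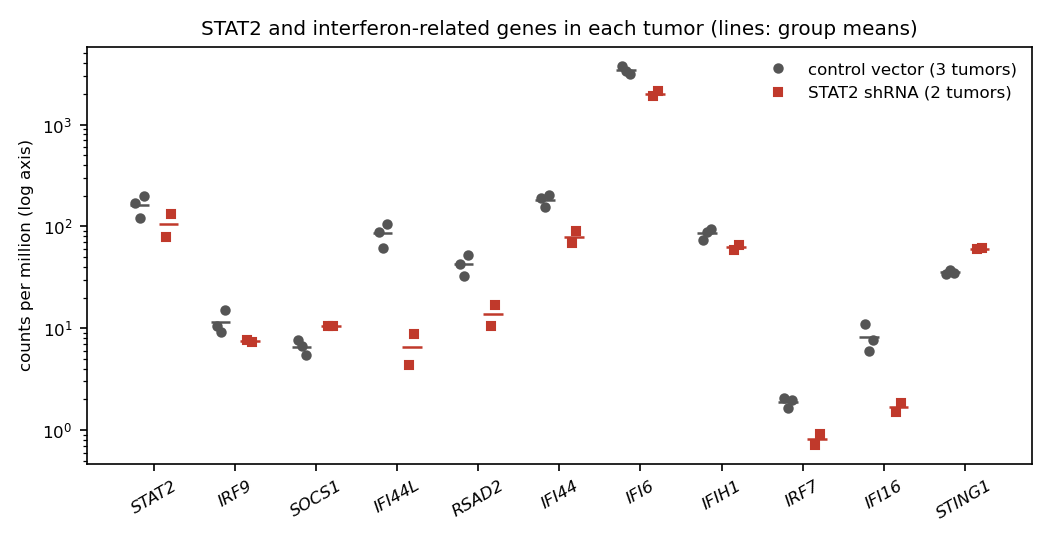
Level in CPM (log axis) of STAT2 and of named interferon-related genes in each of the 5 tumors, with circles for the 3 control vector tumors, squares for the 2 STAT2 shRNA tumors and lines for the group means. The groups overlap for STAT2 and are separate for IFI44L, where controls lie between 61.1 and 106 CPM and shRNA tumors at 4.37 and 8.76 CPM.

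MHC class I antigen presentation could be measured only in part. Of 21 listed genes, 11 were tested, and TAP1, PSMB9 and TAPBP, which lie in the MHC region of chromosome 6, were listed at or near 0 in every library. Among the tested members, B2M, the light chain of class I molecules, stood at 297 ± 90.8 CPM in controls and 219 ± 68.4 CPM in shRNA tumors, and ERAP2, CALR and PSMB10 had log2 fold changes of -0.27, -0.18 and 0.20. No member was called over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, DESeq2 and voom called 0, and camera gave an adjusted p of 0.771. The NF-kB targets had 23 tested members, a median log2 fold change of 0.06 and 0 calls by either count or by DESeq2 or voom, with 3 at an unadjusted p under 0.05 (camera adjusted p 0.771); TRAF1 had a log2 fold change of -0.89, TNFAIP2 0.50, BIRC3 0.53 and BCL3 0.45.

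Over the whole transcriptome, 180 of 16697 tested genes changed between the groups, 117 higher and 63 lower in the tumors labelled STAT2 shRNA. LIPG (ENSG00000101670), which encodes endothelial lipase, fell from 26.7 ± 8.25 CPM (SD, n = 3) to 0.182 ± 0.0874 CPM (SD, n = 2). HS3ST1, a heparan sulfate sulfotransferase, fell from 96.8 ± 8.43 CPM to 8.27 ± 0.522 CPM, and the serotonin receptor gene HTR7 from 117 ± 16.5 CPM to 12.8 ± 4.63 CPM. The hair keratin gene KRT81 (ENSG00000205426) rose from 5.40 ± 2.72 CPM to 212 ± 75.2 CPM and WDR72 (ENSG00000166415) from 0.618 ± 0.146 CPM to 19.2 ± 2.57 CPM. Their log2 fold changes were -7.16 for LIPG, -3.55 for HS3ST1, -3.19 for HTR7, 5.35 for KRT81 and 5 for WDR72.

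All 180 genes changed at least 2-fold, and 167 were protein coding. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, LIPG, WDR72 and HS3ST1 shared the smallest adjusted p, 9.11e-05. In all 180 the groups did not overlap, against 25% of all tested genes and 20% by chance for 3 tumors against 2. The test on these same tumors selects separate groups and large changes, so neither this nor the 2-fold size is added support. At an unadjusted p under 0.05 there were 1560 genes. The number of called genes was 114, 119 and 117 without control A, B or C, 35 without shRNA B and 70 without shRNA C, where the remaining shRNA tumor was assumed to vary like the others. Of the 23 called genes named for their fold or p, 21, 22 and 19 remained called without control A, B or C, 14 without shRNA B and 15 without shRNA C.

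**Figure D2:**
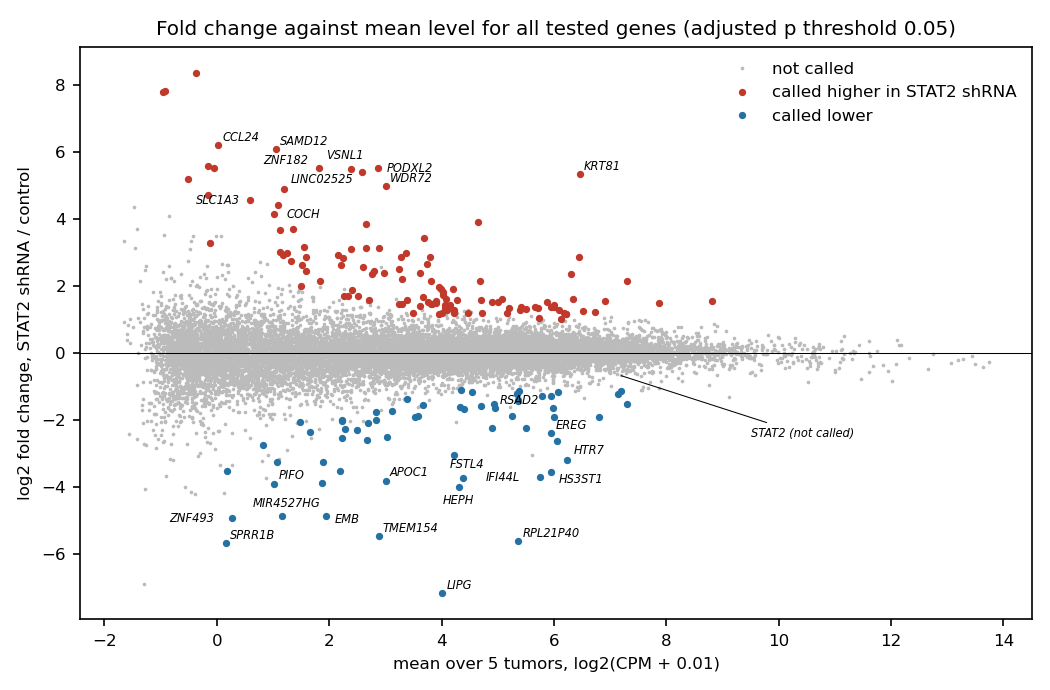
Fitted log2 fold change (STAT2 shRNA over control vector) against the mean level over the 5 tumors, as log2 of CPM plus 0.01, for 16697 tested genes, with 117 genes called higher in red, 63 called lower in blue and the rest in grey. LIPG lies lowest among the called genes at -7.16; the 3 highest points have 0 counts in every control, so their fitted values depend on the prior count.

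Among the largest rises, PODXL2, a sialomucin related to podocalyxin, rose from 0.381 ± 0.158 CPM (SD, n = 3) to 17.7 ± 7.01 CPM (SD, n = 2), the zinc finger gene ZNF182 from 0.171 ± 0.0248 CPM to 8.57 ± 0.953 CPM, and VSNL1, a neuronal calcium sensor, from 0.289 ± 0.162 CPM to 12.6 ± 3.05 CPM. The eotaxin-2 gene CCL24 had 2 counts over the 3 controls and 82 over the shRNA tumors, a ratio of 94.1 with an exact 95% counting interval of 25.2 to 790. SAMD12 had 5 and 167 counts, a ratio of 76.7 (32.2 to 239). LINC02525, the glutamate transporter gene SLC1A3 and COCH had log2 fold changes of 4.90, 4.59 and 4.42. COCH had 0 counts in controls A and B and was not called by DESeq2 (adjusted p 0.426) or with the replicate letter as a block (0.0791). Some of these calls ended with a tumor left out: CCL24 and COCH without shRNA B (adjusted p 0.0676 and 0.238) or C (0.0857 and 0.139), LINC02525 without control C (0.0542) or shRNA C (0.108), and SLC1A3 without control B (0.0556), shRNA B (0.295) or shRNA C (0.134). KRT81 shares near-identical sequence with other hair keratin genes, so its level is uncertain.

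Among the largest falls, HEPH, a ferroxidase of intestinal iron export, fell from 31.9 ± 7.71 CPM (SD, n = 3) to 2.00 ± 1.05 CPM (SD, n = 2), the apolipoprotein gene APOC1 from 12.8 ± 3.96 CPM to 0.904 ± 0.246 CPM, and FSTL4 from 32.9 ± 2.63 CPM to 2.48 ± 0.967 CPM. TMEM154, EMB, MIR4527HG and PIFO had log2 fold changes of -5.45, -4.87, -4.85 and -3.89. Counts were few for SPRR1B, a cornified envelope precursor, with 128 in the controls and 1 in the shRNA tumors, a ratio of 55.8 with an exact 95% counting interval of 9.83 to 2220. ZNF493 had 182 and 2 counts, a ratio of 39.6 (10.8 to 330). Voom did not call TMEM154, EMB or ZNF493 (adjusted p 0.0654, 0.0965 and 0.0673). Without shRNA B the calls of TMEM154 (0.0773), EMB (0.0796), MIR4527HG (0.103), PIFO (0.217), SPRR1B (0.203) and ZNF493 (0.188) ended, and without shRNA C those of EMB (0.108), PIFO (0.0621), SPRR1B (0.212) and ZNF493 (0.253). EMB was also not called without control C (0.0541), and SPRR1B and ZNF493 were not called without control A (0.062 and 0.0812) or control C (0.064 and 0.137). The processed pseudogene RPL21P40 fell from 67.9 ± 19.3 CPM to 1.39 ± 0.613 CPM. Its level is uncertain, since it is a copy of RPL21 and reads of the gene and the copy may not be told apart. Why the groups differ in it was not tested.

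SLC1A3 and EMB lie on chromosome 5, where fold changes shifted over long stretches. The 130 tested genes between 0 and 50 Mb had a median log2 fold change of 0.46, 113 of them positive, and the 67 between 50 and 70 Mb had a median of -0.71, 56 of them negative. The other 559 tested genes of the chromosome had a median of -0.04. Relative to the average control, the median of the first stretch was -0.06, 0.06 and -0.02 in controls A, B and C and 0.46 and 0.48 in shRNA B and C. In the second stretch it was -0.20, 0.04 and 0.12 in the controls and -0.69 and -0.67 in the shRNA tumors. Both stretches were picked after the fold changes had been seen.

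**Figure D3:**
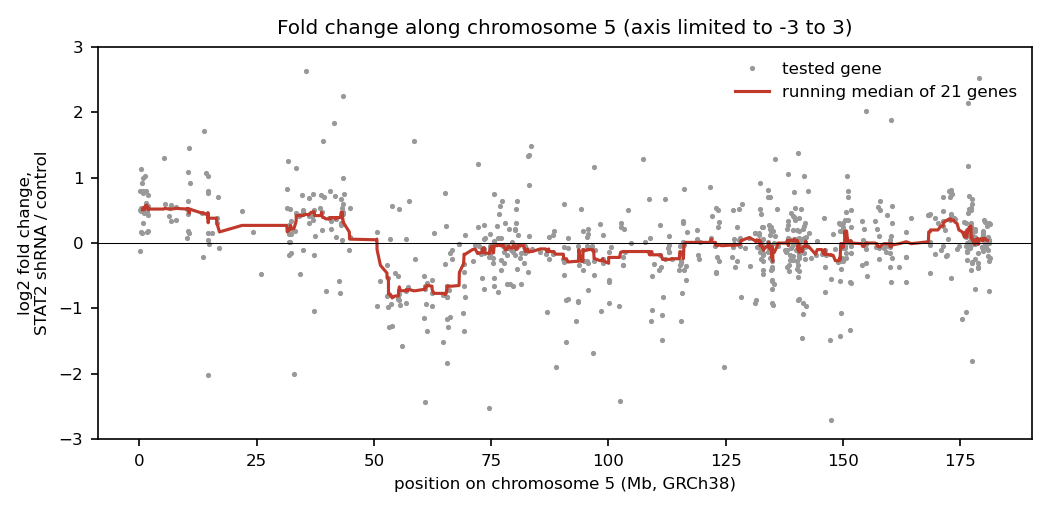
Log2 fold change (STAT2 shRNA over control vector) of each tested gene along chromosome 5 (position in Mb, GRCh38), with the running median of 21 genes as a red line; 5 genes beyond 3 in either direction are outside the axis. The median lies near 0.46 up to 50 Mb, near -0.71 from 50 to 70 Mb and near 0 over the rest.

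Most cell cycle genes stood higher in the tumors labelled STAT2 shRNA. Of 36 tested S-phase and E2F targets, 35 had a positive log2 fold change, with a median of 0.37, and so did 32 of 34 G2/M genes, with a median of 0.34. The thymidine kinase gene TK1 stood at 169 ± 40.5 CPM in controls and 283 ± 90.2 CPM in shRNA tumors, with E2F1, MCM2 and CLSPN at log2 fold changes of 0.77, 0.59 and 0.67. The mitotic phosphatase gene CDC25C stood at 12 ± 2.95 CPM and 24.9 ± 4.17 CPM, with BUB1B, PLK1 and PRC1 at 0.78, 0.81 and 0.62. No single member of either list was called by edgeR over all genes or adjusted over the list alone, nor by voom, while DESeq2 called 0 S-phase and 1 G2/M gene, CDC25C (adjusted p 0.0236), and 7 and 8 had an unadjusted p under 0.05. Camera called both lists higher with adjusted p 3.07e-06, but neither with an estimated correlation, where the adjusted p was 0.782 for both. Host fibroblast and endothelial markers moved the same way, with medians of 0.51 and 0.57.

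Wnt target genes also stood higher, with a median log2 fold change of 0.55 over 16 tested members, 13 of them positive. Host fibroblast and endothelial markers rose by similar amounts, with medians of 0.51 and 0.57. NOTUM, a secreted Wnt inhibitor that Wnt signaling itself induces, rose from 8.10 ± 2.17 CPM (SD, n = 3) to 28.8 ± 12.3 CPM (SD, n = 2), with an adjusted p of 0.0209 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cyclin D1 (CCND1) stood at 347 ± 56.6 CPM and 636 ± 82.5 CPM, TCF7 at 29.7 ± 3.24 CPM and 52.1 ± 4.23 CPM, and TNFRSF19 at 0.237 ± 0.157 CPM and 1.09 ± 0.158 CPM. In edgeR only NOTUM was called over all genes, against 8 higher and 1 lower adjusted over the list alone; voom called 1 member and DESeq2 3, among them CCND1 (adjusted p 0.0106) and TCF7 (0.0327). Camera called the list higher with adjusted p 0.000251, but the adjusted p with an estimated correlation was 0.409. NOTUM itself remained called in 2 of the 5 fits that left out a tumor, with adjusted p between 0.0273 and 0.43.

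Genes downstream of MAPK signaling had fold changes in both directions. EREG and AREG, which encode the EGF receptor ligands epiregulin and amphiregulin, fell from 91.6 ± 38.3 CPM (SD, n = 3) to 17.5 ± 3.87 CPM (SD, n = 2) and from 54.7 ± 10.9 CPM to 20.8 ± 1.61 CPM. DUSP6, an ERK phosphatase induced by ERK, fell from 186 ± 17.6 CPM to 85.2 ± 6.27 CPM. Another ligand of the same receptor, TGFA, stood at 89.7 ± 5.15 CPM and 166 ± 0.938 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.0122 for EREG, 0.0188 for AREG, 0.023 for DUSP6 and 0.0546 for TGFA. These 3 falls were the only edgeR calls over all genes among 20 tested members, against 4 higher and 3 lower adjusted over the list alone, and the list was not called (camera adjusted p 0.837). DESeq2 called 5 members and voom 3; TGFA was called higher by DESeq2 (adjusted p 0.00259), and by edgeR with library-size scaling (0.0475), robust dispersion (0.0483) and protein-coding genes alone (0.0286). EREG remained called in 3, AREG in 2 and DUSP6 in 1 of the 5 fits that left out a tumor, with adjusted p up to 0.217, 0.295 and 0.21.

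Immediate-early genes and cholesterol synthesis genes stood lower. Of 19 tested immediate-early genes, 15 had a negative log2 fold change, with a median of -0.30, and FOS, ZFP36, FOSB and KLF6 had values of -0.62, -0.49, -0.51 and -0.47. Of 24 cholesterol synthesis genes, 18 were negative, with a median of -0.18; STARD4, a sterol transporter, stood at 109 ± 49.8 CPM and 50.8 ± 8.12 CPM, with MSMO1, INSIG1 and IDI1 at -0.66, -0.56 and -0.52. No member of either list was called by edgeR over all genes or adjusted over the list alone, nor by voom, while DESeq2 called 0 and 1 (STARD4, adjusted p 0.0368), and 2 and 4 had an unadjusted p under 0.05. Camera called each lower with adjusted p 0.00992, and the adjusted p with an estimated correlation was 0.782 for both. Without control B the adjusted p was 0.0547 and 0.121, and without shRNA C it was 0.5 and 0.37, for the immediate-early and the cholesterol genes in turn.

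Of 24 tested members of the unfolded protein response and ATF4 list, 19 had a positive and 5 a negative log2 fold change. They had a median log2 fold change of 0.24, with STC2, PHGDH and CHAC1 at 0.75, 0.82 and 1.02, while the endoplasmic reticulum chaperone gene HSP90B1 stood at 1800 ± 293 CPM in controls and 999 ± 153 CPM in shRNA tumors. No member was called by edgeR over all genes (7 at an unadjusted p under 0.05, 0 by voom, and by DESeq2 2, STC2 and HSP90B1, with adjusted p 0.0428 and 0.0156), and 1 was higher and 1 lower adjusted over the list alone. Camera called the list higher with adjusted p 0.00992, the adjusted p with an estimated correlation was 0.782, and the call ended without control B (0.0547) and without shRNA B (0.176). The p53 targets had 27 tested members, a median of 0.00 and 0 calls over all genes, with 1 lower adjusted over the list alone (camera adjusted p 0.771; 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom); TP53INP1 had a log2 fold change of -1.25, TP53I3 -0.66, TIGAR 0.52 and PHLDA3 0.57. TP53INP1 was called lower by DESeq2 (adjusted p 0.00583), and by edgeR over protein-coding genes alone (0.0383) and without control B (0.0472). Among 30 apoptosis regulators, BCL2L1, HRK, BCL2L11 and CASP8 had log2 fold changes of 0.68, 1.10, 0.57 and -0.64, and 0 were called by either count (camera adjusted p 0.756; 5 at an unadjusted p under 0.05, 0 by DESeq2 or voom).

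Among genes of energy metabolism, those encoded in mitochondria stood lower. The 13 mitochondrially encoded genes had a median log2 fold change of -0.41, with MT-ND3, MT-ND2, MT-ATP6 and MT-ND4L at -0.55, -0.55, -0.53 and -0.64, and 0 were called by either count, by DESeq2 or by voom, or had an unadjusted p under 0.05. Camera called them lower with adjusted p 0.00652, against an adjusted p of 0.782 with an estimated correlation, 0.0696 without control C and 0.651 without shRNA B. Their share of counts was 8.2%, 7.6% and 12.3% in controls A, B and C and 6.6% and 8.8% in shRNA B and C. The 46 nuclear-encoded respiratory chain genes had a median of -0.03 and 0 calls by either count (camera adjusted p 0.78, and 0.0114 without control C; 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom). SDHA, on the stretch of chromosome 5 that shifted upward, had a log2 fold change of 0.79 and was called by DESeq2 (adjusted p 0.0215), and SDHD, ATP5MC1 and UQCRC1 had values of -1.04, -0.49 and 0.37.

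Among glucose transporters, SLC2A3 stood at 294 ± 62.1 CPM in controls and 143 ± 7 CPM in shRNA tumors and SLC2A1 at 758 ± 88.9 CPM and 1110 ± 193 CPM, neither called by edgeR over all genes (adjusted p 0.0709 and 0.424). SLC2A3 was called by DESeq2 (adjusted p 0.00192) and by edgeR over protein-coding genes alone (0.0289). The 20 glycolysis genes had 0 calls over all genes and 1 lower adjusted over the list alone (camera adjusted p 0.391, and 0.0426 without shRNA C; 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom), and PKM and HK2 had log2 fold changes of 0.39 and -0.35. The 30 hypoxia genes had a median of 0.08 and 0 calls by either count (camera adjusted p 0.431, and 0.0442 without control C; 3, 1 and 0 by the same counts), with STC2, ANKRD37 and NDRG1 at 0.75, 0.60 and -0.44. The 37 tested cytosolic ribosomal protein genes had a median of -0.04 and 0 calls by either count (camera adjusted p 0.79, and 0.00817 without control C; 0, 0 and 0); RPL22, RPL35 and RPL32 had values of 0.34, -0.30 and -0.28. The 16 housekeeping genes had a median of 0.00 and 0 calls over all genes, with 1 higher adjusted over the list alone (camera adjusted p 0.837; 2, 1 and 0); GUSB and IPO8 had values of -0.55 and -0.31.

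Epithelial and mesenchymal genes had mostly positive log2 fold changes, 16 of 22 and 17 of 22. The 22 tested epithelial genes had a median log2 fold change of 0.17, with the claudin gene CLDN4 at 198 ± 8.97 CPM and 311 ± 74.9 CPM and ELF3, SPINT1 and CLDN3 at 0.50, 0.46 and 0.84. None was called by either count or by DESeq2 or voom, and 4 had an unadjusted p under 0.05 (camera adjusted p 0.0828, 0.0387 with DESeq2 and 0.00776 without shRNA C). The 22 tested mesenchymal genes had a median of 0.22, and LOXL2, MMP9 and CDH2 had log2 fold changes of 0.94, 1.28 and -1.83, none of them called by edgeR, while DESeq2 called LOXL2 (adjusted p 0.0212). Camera called the mesenchymal list higher with adjusted p 0.0148, against an adjusted p of 0.782 with an estimated correlation, 0.512 without control A, 0.0757 without shRNA C and 0.555 with the replicate letter as a block. Its mean log2 level, relative to the average over the 5 tumors, was -0.50, 0.29 and -0.15 in controls A, B and C. In shRNA B and C it was 0.14 and 0.22. The tumors had the same order in the host fibroblast markers. Both lists hold MMP2 and SPARC, so part of this match is built in.

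Markers of host cells varied between tumors of the same group. The 18 tested fibroblast markers had a median log2 fold change of 0.51, with COL1A1 at 378 ± 149 CPM in controls and 596 ± 125 CPM in shRNA tumors and COL5A2, BGN and MMP2 at 1.02, 0.72 and 0.80. Their mean log2 level, relative to the average over the 5 tumors, was -1.23, 0.62 and -0.20 in controls A, B and C and 0.39 and 0.42 in shRNA B and C. Camera called them higher with adjusted p 0.00158, against an adjusted p of 0.81 with an estimated correlation, 0.294 without control A and 0.199 with the replicate letter as a block. The 14 tested endothelial and mural markers had a median of 0.57, with ROBO4, ESAM, CSPG4 and MMRN2 at 1.15, 0.65, 0.60 and 0.79. Camera called these higher with adjusted p 0.00652, against an adjusted p of 0.409 with an estimated correlation and 0.0818 without shRNA C.

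Myeloid markers were not called as a list, with 15 tested members, a median of 0.29 and a camera adjusted p of 0.425, which was 0.00069 without control B and 0.00718 without shRNA B. MPEG1, ITGAM, CD74 and MRC1 had log2 fold changes of 1.25, 0.79, 0.35 and -0.61. The 10 tested muscle, fat and blood markers had a median of -0.52 but a mean of 0.12, and their camera test pointed upward with adjusted p 0.771, or 0.00895 without control B. ADIPOQ had 5 counts over the controls and 36 over the shRNA tumors, while MYH2, LPL and HBB had log2 fold changes of -2.04, 1.74 and -0.79. No member of the 4 host lists was called over all genes or adjusted over the list alone, or by DESeq2 or voom, and 1 fibroblast, 3 endothelial, 0 myeloid and 1 of the last list had an unadjusted p under 0.05. Whether their reads came from human or mouse RNA was not analysed here.

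**Figure D4:**
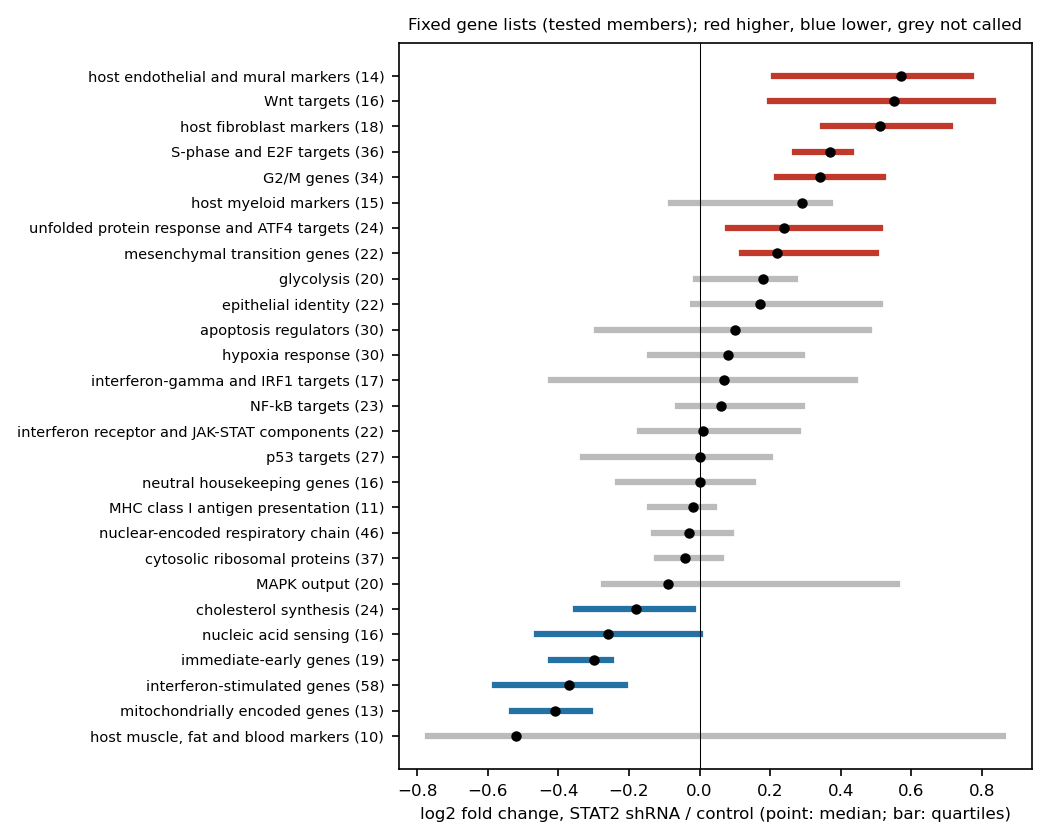
Median (point) and quartiles (bar) of the log2 fold change, STAT2 shRNA over control vector, for the tested members of each of the 27 gene lists, with the number of tested members in brackets. Camera with the preset correlation called 7 lists higher (red) and 5 lower (blue) and 15 were not called (grey); with an estimated correlation 0 were called.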

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

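Thinning control C to the total of control B was chosen after the results were seen, and all other settings before the data were examined. No called result changed direction under any setting, and over all single results and settings 2482 values kept their side of the threshold, 105 lost a call and 30 gained a call. Against 180 called genes, 395 were called by DESeq2 (322 at least 2-fold) and 279 among protein-coding genes alone, where fewer genes were tested; scaling, filters, voom, robust dispersion, mitochondrial genes left out and control C thinned gave 168 to 217. Of the calls, 58% were higher with DESeq2 against 65% of the 180, and the cause was not tested. With the replicate letter as a block, 87 genes were called, all at least 2-fold and 83 of them shared. The labels do not say that a letter marks a shared batch. Deviations of same-letter tumors from their group means correlated at -0.16 for B and -0.23 for C. With 2 shRNA tumors the deviations mirror each other, so these values cannot decide whether the letters pair the tumors. Leaving out a library gave 35 to 119 called genes (at least 2-fold, 35 to 119), with fewer samples; 34 of the 35 genes without shRNA B and 68 of the 70 without shRNA C were shared with the 180. STAT2 had log2 fold changes of -0.29 to -1.08 with a library left out, and was called in no setting. For interferon-stimulated genes, the adjusted p was 0.409 with an estimated correlation (0.097 against the preset 0.01), 0.135 with fry and at most 5.05e-05 in every other setting. The number of called lists fell from 12 to 0 with an estimated correlation and with fry's test of a single direction, and other settings called 10 to 13. A correlation above the preset cannot account for every loss. The endothelial and mural markers had an estimated correlation of -0.027, below the preset 0.01, and their camera adjusted p still went from 0.00652 to 0.409. With an estimated correlation, camera also takes its degrees of freedom from the 5 tumors and not from the number of genes. This tends to raise the p-value of any list. A call lost with that setting therefore does not measure how far the members vary together. The share of each part was not tested. Depth limits low genes most, because 4 of the 5 libraries hold between 12668800 and 17008794 counts.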

Other observations

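The tests on host and skin cells, on STAT2 order, on chromosome 5, on RPS18 and on the leukocyte receptor complex, and the thinning of control C, were chosen after the results were seen, as were the genes named in the next 3 paragraphs, except KRT81.

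Keratin genes of the type II cluster on chromosome 12 rose together in the tumors labelled STAT2 shRNA. Of 14 tested keratins there, 8 were called higher, with a median log2 fold change of 2.91, and DESeq2 and voom also called 8. Of 10 keratins on chromosome 17, edgeR and voom called 0, but 2 had an unadjusted p under 0.05 and were called by DESeq2, KRT13 (4.02-fold higher, edgeR adjusted p 0.0686) and KRT16 (2.07-fold, 0.109). The called keratins on chromosome 12 lie between KRT80 (starting at 52168996) and KRT4 (ending at 52814551, GRCh38). KRT6B rose from 24.8 ± 7.22 CPM (SD, n = 3) to 182 ± 99.6 CPM (SD, n = 2), KRT7 from 29.5 ± 9 CPM to 153 ± 67.9 CPM, KRT80 from 65.9 ± 9.10 CPM to 296 ± 63.8 CPM and KRT75 from 2.62 ± 1.46 CPM to 28.1 ± 13.0 CPM. In the same cluster KRT5, KRT8 and KRT18 were not called by edgeR or DESeq2, with log2 fold changes of 0.22, 0.51 and 0.37. KRT6A and KRT6B, and KRT81 and KRT86, are near-identical pairs whose reads cannot be assigned with certainty.

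Called genes lay near each other more often than random sets of tested genes. Of 180 called genes, 35 had another called gene with the same direction within 500 kb, against a median of 12 in 10000 permutations (p = 2e-04). Without the called keratins it was 27 of 172 (p = 0.002, permutation). Neighboring genes of other families and overlapping genes were not removed, so the count does not show that whole regions changed together.

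Other called genes encode carriers, enzymes, receptors and secreted factors. CRABP2, a retinoic acid carrier, rose from 251 ± 71.0 CPM (SD, n = 3) to 745 ± 45.7 CPM (SD, n = 2), STRA6, a retinol transporter, from 3.85 ± 1.04 CPM to 28.7 ± 9.91 CPM, and CYP24A1, which inactivates vitamin D, from 2.76 ± 1.01 CPM to 20.1 ± 2.84 CPM. The complement gene C3 rose from 44.3 ± 4.39 CPM to 136 ± 21.5 CPM, and TNFSF9, the ligand of the T cell costimulator 4-1BB, from 135 ± 30.8 CPM to 380 ± 20.2 CPM. BAMBI, a decoy receptor of the TGF-beta family, fell from 99.5 ± 13.0 CPM to 16.2 ± 3.64 CPM, while SMAD6, an inhibitor of BMP signaling, rose from 8.25 ± 1.40 CPM to 22.7 ± 4.26 CPM. With 0 counts in all 3 controls, MAGEC2, ZNF595 and ZNF831 were at least 48.2-fold, 32.9-fold and 32.1-fold higher over the shRNA tumors, against a floor of 3 counts over the control group.

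For the 180 calls, gains or losses of chromosome stretches are argued against as the whole cause, since windows of 10 Mb with a median log2 fold change beyond 0.4 held 4.73% of the 169 called genes that lay in windows with at least 20 tested genes, and so is the depth of control C, since 185 genes were called with it thinned. For host cells, the 57 host markers had a median of 0.37 and an upper quartile of 0.72, and 0 were called. The genes that rose had a lower quartile of 1.45. They were selected for their change and all rose at least 2-fold, so the comparison cannot exclude host cells for some calls. It shows only that the host markers as a set did not rise as far. For the keratins, 11 skin markers had a median of -0.17, with DMKN at 341 ± 9.30 CPM and 302 ± 23.7 CPM. Among them 2 were called lower, DSC3 and COL17A1 (log2 fold changes -3.25 and -1.51), and 0 were called higher. Whether tumor or host cells gave these reads was not analysed, so skin cells stay open as well. The 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05; 1 split, the real one, gave 180 calls, and the highest of the others gave 7. For chromosome 5 a few strongly changed genes are argued against, since 85.8% of the tested genes went in the direction of their stretch. Over the genome, 267 windows held at least 20 tested genes, and 6 had a median beyond 0.4, all on chromosome 5. The largest median outside the stretches was -0.32. These values go with a copy number difference between the 2 cell lines, but copy number was not analysed here and this stays open. That 2 of 2 shRNA tumors lay outside all 3 controls adds nothing, because the stretches were picked for that shift. Still open for the other calls are host cells for some, an effect of the shRNA, or a line difference from before implantation. This design of 1 line per group does not separate the shRNA from the line.

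For the lower interferon-stimulated genes, the slope on the fibroblast markers within the 3 controls predicted 1.36% of the group difference. Over those 3 tumors the fibroblast score ranged over 1.85 and the list score over 0.12, against a group difference of -0.44. This speaks only to fibroblasts and rests on 3 tumors, so it leaves host cell content open. Endothelial and myeloid content was not tested this way. Of 10000 random lists of the same size and expression, 0 had a median as low as -0.37 (lowest -0.15). Random lists ignore correlation between members, however. The list's adjusted p was 0.409 in camera with an estimated correlation, a setting that also lowers its degrees of freedom. It was 0.135 in fry's test of a single direction. STAT2 transcript and the list had the same order of tumors within each group (controls C, A, B and shRNA C, B), but not between groups: shRNA C, with more STAT2 than control B, had a list score of -0.31 relative to control B on the log2 scale, but this is a single pair of tumors and protein was not analysed here. An effect of STAT2 silencing and another difference between the 2 cell lines cannot be told apart, because each group is 1 line.

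Genes of the MHC region were listed near 0 in every library: 93.3% of its protein-coding genes had under 10 counts over the 5 libraries, against 27.1% on the rest of chromosome 6. Silence of these genes in the tumors is argued against for the region as a whole, since RPS18, a ribosomal protein gene that every cell uses, had at most 2 counts in any library. In the leukocyte receptor complex on chromosome 19, which like the MHC has many alternate sequences in this genome build, 97.4% of protein-coding genes had under 10 counts, against 27.8% on the rest of the chromosome. Reads lost because they also match alternate haplotype sequences could give this. The complex was counted as all 38 protein-coding genes between 54 and 55 Mb, chosen by position and not by function. Silence of the leukocyte receptor genes among them could also lower their counts. That was not tested, so the complex does not tell the 2 explanations apart. No other biological explanation was tested.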
